A study of Rattus norvegicus with 14 samples.

How the data were processed

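Genomic DNA of rat oesophagus was digested with MspI, fragments above 300 bp were removed, the DNA was bisulfite-converted, and libraries were made with a methylation sequencing kit for converted DNA, per the labels' protocols. Per the submitters' processing notes, Trim Galore, FastQC, Bismark 0.23.0 and methylKit 1.14.2 were used with the assembly mRatBN7.2; the notes give the tools no roles or order. The deposited files hold, for each CpG cytosine on each strand, the count of methylated reads, the count of all reads and the methylation in percent. The deposited percent equals the ratio of those counts, truncated. Only cytosines with at least 5 reads were listed in every file, which was checked on the values. Both counts were used as deposited, without normalization, and methylation in percent was recomputed from the deposited counts.

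Of 14 samples, 13 had a file and were analysed: NSC 4, day 1 5 and week 1 4. Groups were taken from the label that gives the time. Replicates were numbered in accession order, so they pair no samples. The labels do not say that samples came from separate animals, so p-values measure the spread between these samples, which may be partly technical. Over the tiles the ratio of chi-square to its degrees of freedom ran from 3.26 to 28.9 for pairs of libraries. A read that covers several cytosines is counted at each of them. The ratio takes these counts as independent and can exceed 1 without a difference, so it does not show disagreement beyond sampling noise. Library titles carry the same run code for every sample, and no batch was given; sample codes run in order of group, so any effect of processing order could not be separated from group.

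Tests used CpG cytosines on chromosomes 1 to 20, X and Y. Cytosines with at least 10 reads in all 13 libraries were summed in 1000 bp tiles counted from position 1, and tiles with at least 3 such cytosines were kept. Methylated and unmethylated counts per tile were tested with edgeR 4.0.16 (R 4.3.3): one effect per library plus group effects on the methylated count, a common dispersion, a quasi-likelihood fit with all 3 groups and an F test per contrast. A tile was called at a Benjamini-Hochberg adjusted p below 0.05 and a difference of group mean percent of at least 10 points. Mean CpG methylation counts each cytosine once and was compared by exact two-sided permutation tests. These choices, and the rule for named tiles, were made before the data were examined. The test had been picked beforehand as the best of several on simulated counts. The SE given for a log2 odds ratio is its absolute value divided by the square root of the F statistic. It is an approximation and was not taken from the fit. The named tiles are the 3 with the largest increase and the 3 with the largest decrease in each contrast against NSC among called tiles whose groups do not overlap. The same rule was applied to the wider set of tiles after the data had been seen, and the report gives part of those it named.

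Promoters, gene lists, genomic features and CpG islands had also been planned, with 21 gene lists, and the rule for named tiles had asked for a nearby gene. None of these was run, because annotation of the assembly used by the files was not used here and coordinates were not converted. The condition on a nearby gene was dropped for that reason.

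The test was also run on 904 simulated tiles with 200 changed between day 1 and NSC. An adjusted p below 0.05 alone marked 80 of 100 tiles changed by a log2 odds ratio of 1, 100 of 100 changed by 2, and 8 unchanged tiles. With the 10 point minimum as well, 154 tiles were called, 0 of them unchanged. In the 14484 tiles of the wider set, again with 200 changed, the adjusted p alone marked 3 and 58 of 100 and 4 unchanged tiles. In the data 2491 tiles of that set were called at day 1, and recovery after adjustment depends on how many tiles change. These counts therefore do not give the power in the real wider set. Changed tiles were drawn only from those whose mean methylation was neither very low nor very high. With the minimum, 60 were called there, 1 of them unchanged. Alternatives were minimum reads of 5 and 20, a limit at the 99.9th percentile of coverage, thinning to 10 reads, cytosines in at least 3 libraries of each group, at least 5 cytosines per tile, 500 bp tiles, limma 3.58.1 on percent, the same after centring each library, quasi-binomial regression, differences of 25 or 0 points, only the groups compared, and leaving out each library. Methylation classes (first by the mean of the 3 groups, then by the midpoint of the groups compared, and by a pair of NSC libraries with the other pair as controls), density classes, chromosomes, mitochondrial reads, unplaced scaffolds and 3 further alternatives for tiles were chosen after seeing the data. Other splits of the libraries, at most 100 per contrast, and 50 simulated unchanged data sets were also run. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Reads carry no molecular identifiers, so intervals for read shares cover counting error only. They also take the counts of neighbouring cytosines as independent and may be too narrow. Depth limits the main set to 7716 of the 12363002 cytosines listed in any library.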

Results

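Reduced representation bisulfite sequencing was used to read DNA methylation in rat oesophagus before and after a surgical defect was repaired with an acellular bi-layer graft of silk fibroin. The libraries fell into 3 groups: full-thickness oesophagus of non-surgical controls (NSC, 4 libraries), host tissue within 2 mm of the defect at 1 day after surgery (day 1, 5 libraries) and new tissue from the graft area at 1 week (week 1, 4 libraries). The fifth week 1 sample was not analysed here. The donors were male rats of 8 to 9 weeks. The files listed 1432898 to 4181382 CpG cytosines per library. Read counts summed over these cytosines were 9676493 in the shallowest library (day 1 replicate 2) and 49782600 in the deepest (NSC replicate 1). A set of 7716 cytosines on chromosomes 1 to 20, X and Y had at least 10 reads in all 13 libraries, and the median number of reads at them ran from 15 (day 1 replicate 2) to 91.5 (NSC replicate 1). They gave 904 tiles of 1000 bp with at least 3 cytosines each. Positions are those of the mRatBN7.2 assembly. Gene annotation of that assembly was not used here, so regions are given by position and no gene, promoter or intron is assigned to them.

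The first comparison asked how methylation of the tissue at the wound margin 1 day after repair differed from that of the unoperated oesophagus. Mean CpG methylation was higher at day 1. It was 61.6% ± 0.47 (SD, n = 5) at day 1 and 58.5% ± 0.15 (SD, n = 4) in NSC, a difference of 3.11 percentage points (exact two-sided permutation test, p = 0.0159, the smallest this design allows). Every one of the 5 day 1 libraries lay above every NSC library. Reads pooled gave 6.83 points and each library's own cytosines with 10 reads gave 10.4 points. The value from own cytosines compares different cytosines in each library, so it does not measure a change at the same cytosines. Day 1 replicate 2 had 10 reads at 7.79% of its listed cytosines, against 32.1% to 40.4% in the NSC libraries. Cytosines were also grouped by their methylation, in 3 ways chosen after the data had been seen. The first grouping used the mean of the 3 group means, which gives the post-operative groups more weight, and after its results were known it was replaced by the midpoint of the groups compared. With the midpoint, the differences were as follows. The 2318 cytosines at 70 to 90% were at 78.5% in NSC and 84.9% at day 1, a difference of 6.34 points. The 1353 cytosines at 30 to 70% were higher at day 1 by 4.75 points and the 2018 at 90 to 100% by 1.46 points. Each of these differences had an adjusted p of 0.0476 over 15 exact permutation tests, and of 0.0595 with at least 5 reads per cytosine, where none of them passed. The exact permutation p cannot be below 0.0159 here, so passing also depends on how many of the 15 tests reach their smallest p. Passing at one depth and not at the other therefore does not show a smaller difference. The classes under 10% and at 10 to 30% did not pass, with differences of 0.241 and -1.11 points. The third grouping set classes on a pair of NSC libraries with the other pair as controls and was not tested. Over the 3 groupings with 10 and with 5 reads, the 8 values ran from 2.93 to 8.20 points at 70 to 90%, from 4.72 to 9.49 points at 30 to 70%, from 0.766 to 1.98 points at 90 to 100% and from 0.00245 to 1.16 points under 10%. At 10 to 30% they ran from -3.69 to 8.93 points, so no direction is given there. With the first grouping 4 of the 5 classes had passed at 10 and at 5 reads, that at 10 to 30% among them (-3.69 points, adjusted p = 0.0397, exact permutation test, with 10 reads).

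**Figure D1:**
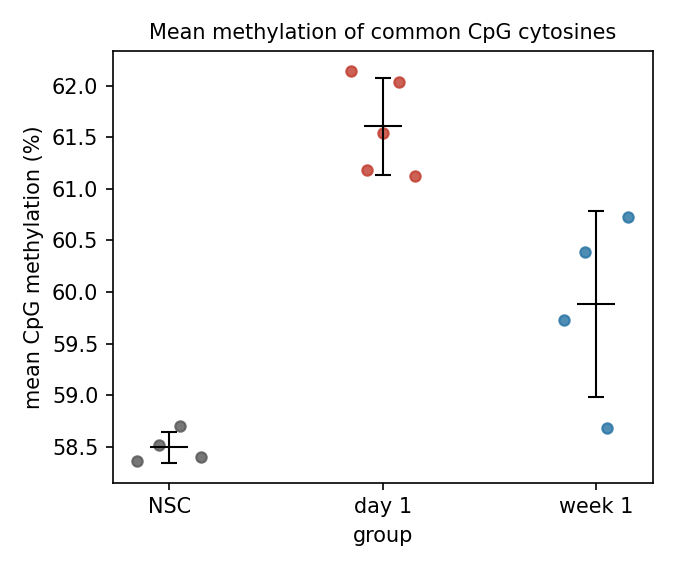
Mean methylation (percent) of the 7716 CpG cytosines with at least 10 reads in all libraries, by group. Each point is a library, the long bar is the group mean and the whiskers are 1 SD, and the axis does not start at 0. The 5 day 1 libraries lie between 61.1% and 62.1%, above the 4 NSC libraries at 58.4% to 58.7%.

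Of the 904 tiles, 162 differed between day 1 and NSC, 123 of them higher and 39 lower at day 1 (edgeR quasi-likelihood test, adjusted p below 0.05 and a difference of at least 10 points). With a difference of at least 25 points, 22 were higher and 19 lower, and limma after centring each library called 99 higher and 45 lower. The median absolute difference of the called tiles, which the 10 point minimum raises, was 18.9 points, and the median difference over all 904 tiles was 2.18 points, or 1.29 to 3.34 points over all settings except centring. In 84.6% of the 162 no day 1 library overlapped the NSC libraries. Chance alone leaves 1.59% of tiles without overlap, and 238 of all 904 tiles had none. Tiles that were higher at day 1 had a median NSC methylation of 60.9% and a median day 1 methylation of 81.7%. For tiles that were lower, the medians were 55.8% and 23.3%.

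The largest loss of methylation at day 1 among tiles without overlap lay on chromosome 2 at 185531001 to 185532000. Its methylation was 78.6% ± 3.63 (SD, n = 4) in NSC and 16.7% ± 5.30 (SD, n = 5) at day 1, with a log2 odds ratio of -4.20 ± 0.28 (SE) and an edgeR adjusted p of 2.61e-08. All 4 of its cytosines, from 185531122 to 185531256, moved the same way, and read counts summed over them were 146 to 902 per library. A tile on chromosome 10 at 105906001 to 105907000 was at 81.4% ± 4.97 (SD, n = 4) in NSC and 21.9% ± 18.6 (SD, n = 5) at day 1. A tile on chromosome 8 at 96975001 to 96976000 was at 82.5% ± 2.04 (SD, n = 4) in NSC and 26.0% ± 11.7 (SD, n = 5) at day 1. The largest gain lay on chromosome 10 at 81286001 to 81287000, with 13.4% ± 5.74 (SD, n = 4) in NSC and 63.7% ± 6.90 (SD, n = 5) at day 1 (log2 odds ratio 3.55 ± 0.40 (SE), edgeR adjusted p = 6.96e-06). Chromosome 20 at 10974001 to 10975000 rose from 25.2% ± 5.25 (SD, n = 4) to 72.7% ± 9.71 (SD, n = 5), and chromosome 2 at 174639001 to 174640000 from 45.9% ± 6.04 (SD, n = 4) to 84.2% ± 10.7 (SD, n = 5). In all 6 tiles every measured cytosine moved in the direction of the tile.

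The second comparison asked whether the new tissue of the graft area at 1 week differed from unoperated oesophagus. Here 115 of the 904 tiles differed, 76 higher and 39 lower at week 1 (edgeR quasi-likelihood test, same thresholds), with a median absolute difference of 19.7 points under that minimum and a median difference of 0.760 points over all 904 tiles, or 0.221 to 1.66 points over all settings except centring. With at least 25 points, 17 were higher and 16 lower, and after centring 68 were higher and 45 lower. In 107 of them no week 1 library overlapped the NSC libraries. Chance leaves 2.86% of tiles without overlap, and 219 of all 904 tiles had none. Mean CpG methylation was 59.9% ± 0.90 (SD, n = 4) at week 1, 1.39 points above NSC, and this difference did not pass (exact two-sided permutation test, p = 0.0571). Week 1 replicate 3, at 58.69%, lay within the NSC range of 58.36% to 58.70%, and the other week 1 libraries lay above it. Without that library the difference was 1.79 points (exact permutation p = 0.0571, the smallest possible for the libraries left). With all 4 week 1 libraries the difference passed with at least 5 reads per cytosine (2.07 points) and with reads pooled (3.65 points). It also passed with 10 reads drawn at each cytosine (1.31 points), each with an exact permutation p of 0.0286. It did not pass with at least 20 reads (0.826 points, exact permutation p = 0.171) or with each library's own cytosines (5.50 points, exact permutation p = 0.286). Differences by methylation class varied with the grouping and the depth. The smallest exact permutation p for 4 against 4 libraries is 0.0286, so passing after adjustment also depended on how many other tests reached their smallest p. By exact permutation tests, 0 of 5 classes passed with the midpoint grouping at 10 or at 5 reads, while 3 passed with the first grouping at 10 reads and 4 at 5 reads. Over all 3 groupings the values ran from 2.29 to 6.76 points at 30 to 70% and from 0.417 to 5.20 points at 70 to 90%. They took both signs in the other classes, with -3.61 to 7.67 points at 10 to 30%, -0.683 to 0.904 points at 90 to 100% and -0.0317 to 1.02 points under 10%.

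The largest loss at week 1 was again the chromosome 2 tile at 185531001, at 12.6% ± 3.32 (SD, n = 4) against 78.6% ± 3.63 (SD, n = 4) in NSC (log2 odds ratio -4.65 ± 0.31 (SE), edgeR adjusted p = 2.57e-08). The tile on chromosome 19 at 54823001 to 54824000 fell from 54.5% ± 4.36 (SD, n = 4) to 2.29% ± 3.71 (SD, n = 4), with summed read counts of up to 1831 per library. The tile on chromosome 3 at 143478001 to 143479000 fell from 63.8% ± 4.29 (SD, n = 4) to 18.1% ± 9.79 (SD, n = 4). The largest gain was the chromosome 10 tile at 81286001, at 58.9% ± 15.9 (SD, n = 4) against 13.4% ± 5.74 (SD, n = 4) in NSC. Chromosome 1 at 181356001 to 181357000 rose from 46.4% ± 7.44 (SD, n = 4) to 87.2% ± 4.85 (SD, n = 4), and chromosome 13 at 96281001 to 96282000 from 28.3% ± 11.7 (SD, n = 4) to 66.7% ± 10.2 (SD, n = 4).

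The differences from NSC at both times were largely in the same tiles and the same direction. The calls shared 69 tiles that were higher and 32 that were lower at both times, and 0 tiles were called in opposite directions. Independent lists of these sizes would share 10.3 higher and 1.68 lower tiles. Both comparisons use the same NSC libraries, so part of the agreement comes from them. With NSC replicates 1 and 2 set against day 1 and replicates 3 and 4 against week 1, 47 higher and 25 lower tiles were shared, and with the NSC pairs exchanged 46 and 26. Simulated unchanged groups against simulated controls shared 0 tiles on average over 50 draws. They also called almost none, on average 0.02 higher and 0.02 lower at day 1 and 0 at week 1. That count therefore does not show how much overlap shared controls add among called tiles. Across tiles, which are not independent replicates, the differences at both times had r = 0.90 and a covariance of 92.8 squared points, beside r = 0.50 and 5.50 squared points in the simulation. With the controls split, r was 0.78 and 0.80 and the covariance 85.9 and 86.9.

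**Figure D2:**
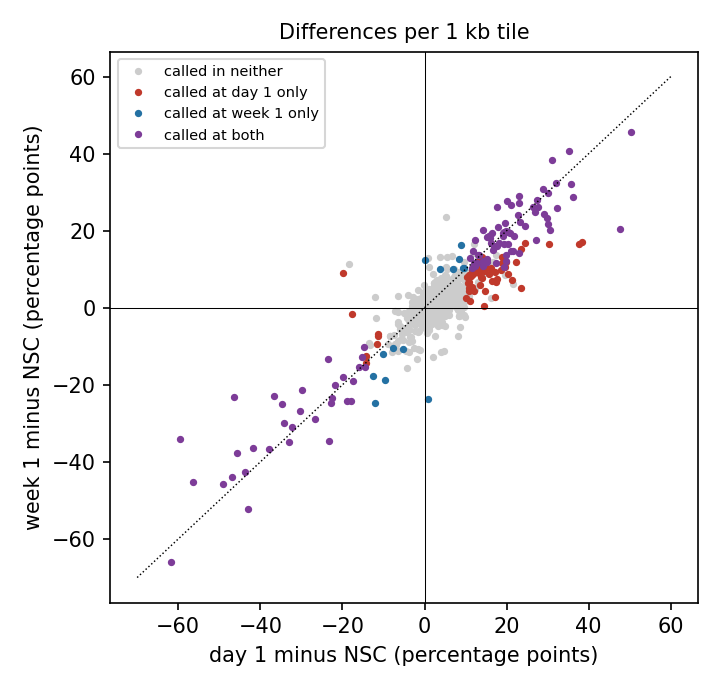
Difference from NSC in percentage points at day 1 (horizontal axis) and at week 1 (vertical axis) for the 904 tiles, coloured by the comparison that called them. The dotted line marks equal differences, and the 101 tiles called at both times lie in the quadrants of equal sign.

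The third comparison asked how the graft tissue at 1 week differed from the wound margin at 1 day. Few tiles were called: 3 of 904, with 2 higher and 1 lower at week 1 (edgeR quasi-likelihood test). By the same test 125 tiles had an unadjusted p below 0.05, and limma on methylation percent called 4. In 59 of all 904 tiles these groups did not overlap, where chance leaves 1.59% of tiles, so a low count of calls does not show that few tiles differ. Over all 904 tiles the median difference was -0.992 points and 31.3% of tiles were higher at week 1, so the called tiles do not represent the whole set. In the same libraries the mean was lower at week 1 by 1.72 points (59.9% against 61.6%, exact two-sided permutation test, p = 0.0159). By the same exact permutation test it did not pass with reads pooled (p = 0.111) or with every cytosine of a library that had 10 reads (p = 0.222). With the midpoint grouping, cytosines at 30 to 70% differed by -2.83 points at week 1 and those at 70 to 90% by -3.42 points (adjusted p = 0.0476 each, exact permutation tests), and with 5 reads neither passed (adjusted p = 0.159 and 0.0595, exact permutation tests). With the first grouping, by the mean of the 3 groups, 3 of 5 classes passed at 10 reads and 1 at 5 reads. The 3 tiles were named after their values had been seen. The tile on chromosome 18 at 68973001 to 68974000 was at 78.98% ± 3.44 (SD, n = 4) in NSC, 79.9% ± 3.10 (SD, n = 5) at day 1 and 55.3% ± 6.91 (SD, n = 4) at week 1 (week 1 against day 1: edgeR adjusted p = 0.000952). Chromosome 15 at 28212001 to 28213000 was at 34.6% ± 4.34 (SD, n = 4) in NSC, 14.7% ± 6.94 (SD, n = 5) at day 1 and 43.6% ± 8.66 (SD, n = 4) at week 1 (edgeR adjusted p = 0.00685). Chromosome 1 at 123990001 to 123991000 was at 24.1% ± 6.67 (SD, n = 4), 6.50% ± 4.63 (SD, n = 5) and 22.6% ± 2.70 (SD, n = 4), with an edgeR adjusted p of 0.0438 for week 1 against day 1. That last call was lost in 18 of 24 alternatives. Over all 24, those that kept the call included, the adjusted p by the test of each alternative ran from 0.0193 to 0.628. Tissue site and time differ together between these 2 groups, so they cannot be separated in this comparison.

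**Figure D3:**
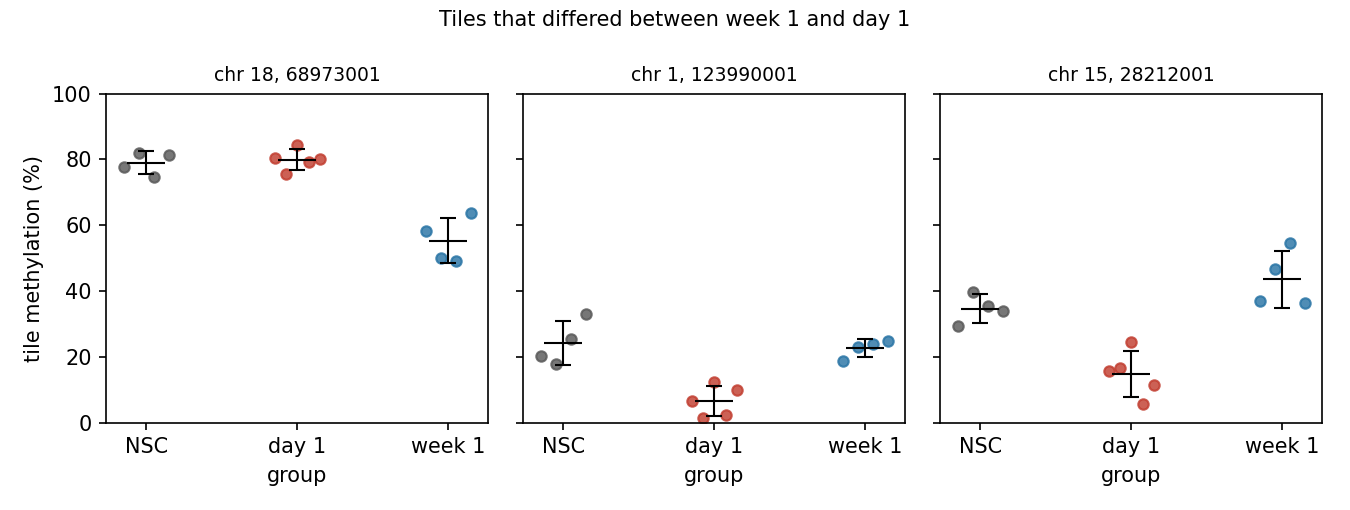
Methylation (percent, axis from 0 to 100) of the 3 tiles that differed between week 1 and day 1, with points for libraries, long bars for group means and whiskers for 1 SD. On chromosome 18 only week 1 lies low, at 55.3%, while on chromosomes 1 and 15 day 1 lies low, at 6.50% and 14.7%.

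In a wider set of 14484 tiles, built from cytosines with at least 10 reads in at least 3 libraries of each group, 2044 tiles were higher and 447 lower at day 1 than in NSC, and 1163 were higher and 391 lower at week 1 (edgeR). The mean over 39168 cytosines with 5 reads in all libraries was above NSC on each of 22 chromosomes at day 1, by 2.51 to 4.55 points, and at week 1, by 0.0803 to 3.12 points, and week 1 lay below day 1 on each of the 22, with differences of -3.64 to -0.479 points. The largest loss at day 1 in the wider set lay on chromosome 12 at 22503001 to 22504000, with 94.4% ± 5.07 (SD, n = 4) in NSC, 18.2% ± 5.77 (SD, n = 4) at day 1 and 55.8% ± 14.7 (SD, n = 4) at week 1. Its summed read counts were 11 to 102 per library. The largest gain lay on chromosome 7 at 51128001 to 51129000, with 22.5% ± 9.15 (SD, n = 3) in NSC and 91.5% ± 11.1 (SD, n = 3) at day 1. At week 1 the largest loss lay on chromosome 1 at 95724001 to 95725000, with 86.1% ± 12.2 (SD, n = 4) in NSC and 16.2% ± 15.2 (SD, n = 4) at week 1, and the largest gain on chromosome 2 at 76114001 to 76115000, with 19.5% ± 15.3 (SD, n = 4) and 85.9% ± 8.03 (SD, n = 3). The tile on chromosome 9 at 60897001 to 60898000 was at 23.9% ± 6.82 (SD, n = 4) in NSC, 87.7% ± 1.95 (SD, n = 4) at day 1 and 87.8% ± 6.13 (SD, n = 4) at week 1.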

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

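All tests of explanations in this part were chosen after the results they bear on had been seen, and so were the counts of other splits.

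Tiles differed between NSC and both post-operative groups. Chance assignment of libraries is unlikely to account for the tiles called against NSC, though so few splits cannot exclude it. Of 100 splits of the 9 libraries, 1 gave as many tiles as the 162 called between day 1 and NSC. Of 35 splits, 1 gave as many as the 115 between week 1 and NSC. Of 100 splits, 1 gave as many as the 3 between week 1 and day 1. The real split was the 1 in each case. The highest other splits gave 127, 0 and 1 tiles. The split with 127 tiles had placed day 1 replicate 5 with all 4 NSC libraries. For week 1 against day 1 the test compares 3 tiles with at most 1, and alternative settings called 0 to 6 tiles. Other splits were counted in the main setting only, so chance stays open for that contrast. The greater depth of the NSC libraries does not account for the pattern as a whole: with 10 reads at every cytosine in every library, day 1 against NSC still called 111 tiles and week 1 against NSC 75. Week 1 had 115 before and the shared tiles went from 101 to 58; the median differences over all tiles were then 2.17 and 0.833 points, against 2.18 and 0.760 points. A lower share of muscle in the tissue taken after surgery may contribute. NSC samples were full-thickness, and mitochondrial reads, used here as a rough proxy for muscle, made up 1.03% ± 0.329 (SD, n = 4) of NSC reads, 0.345% ± 0.158 (SD, n = 5) at day 1 and 0.223% ± 0.111 (SD, n = 4) at week 1 (exact permutation p = 0.0159 and 0.0286 against NSC). Files list only cytosines with at least 5 reads, so this share may also depend on depth, and the shallowest library, day 1 replicate 2, has the highest post-operative share (0.528%). Shallow libraries list fewer nuclear cytosines, which may raise their share and bias the first correlation below. This was not tested. Within NSC the order was the opposite, with 1.46% in the deepest library (replicate 1) and 0.733% in the shallowest (replicate 4). Among the 9 post-operative libraries the mitochondrial share and the position of a library toward NSC had r = 0.248 (permutation p = 0.519) and rho = 0.30 (permutation p = 0.438), and r = 0.504 without the 2 libraries farthest from the median share. A second measure, mitochondrial reads over reads at common nuclear cytosines, gave r = 0.00800 (permutation p = 0.981), rho = 0.10 (permutation p = 0.813) and r = 0.221 without the 2 farthest; over these 2 relations the adjusted p was 0.981 for both r and 0.813 for both rho. Both relations pool day 1 and week 1. Week 1 had the lower mean share, yet its libraries lay mostly closer to NSC, which can lower a pooled r. Correlations within each group were not computed, so the pooled values do not decide the question. With so few libraries the muscle share and the response to surgery cannot be told apart, and the site of sampling stays open as an untested biological difference.

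Mean methylation was higher at day 1 than in NSC. Incomplete bisulfite conversion would add most at cytosines with low methylation, but with cytosines grouped by the midpoint of both groups those under 10% rose by 0.241 points against 4.75 points at 30 to 70%. The gap between these classes was 4.51 points wider at day 1 (exact permutation p = 0.0159), which argues against it as the whole cause. With classes by the mean of the 3 groups, used first, the rises were 0.132 and 4.72 points, and with classes set on a pair of NSC libraries and the other pair as controls they were 0.936 and 7.34 or 1.16 and 7.86 points. The bounds written down for this test, after a look at a wider set, were a rise under 0.5 points below 10% and over 5 points at 30 to 70%; no grouping with 10 reads met both. With 5 reads the midpoint classes (0.0795 and 7.19 points) and those by the mean of the 3 groups (0.00245 and 6.64 points) met both, and the classes set on NSC pairs did not (0.749 and 9.18, 0.872 and 9.49 points). The reading therefore rests on the order of the classes, which was the same in all 3 groupings with 10 and with 5 reads, and a small contribution is not excluded. A response to surgery, a change of cell types and the site of sampling stay open.

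Day 1 replicate 2 had mitochondrial methylation of 1.91% (Wilson 95% interval 1.79% to 2.03%), far from the other day 1 libraries and above every NSC library, whose values ran from 0.173% to 0.259%. Day 1 replicate 1 was also above them, at 0.673% (0.606% to 0.747%). Poor conversion of the whole library would raise nuclear cytosines under 10% (by the mean of the 3 groups) in replicate 2 as well, but they lay -0.123 points from the mean of the other 4 day 1 libraries. This excludes that explanation for replicate 2, and no biological explanation was tested.

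Chance marks about 1 in 20 groups as holding a distant library, and 6 of 78 groups tested held one. The others were the share of reads on chromosome Y in day 1 replicate 2 (0.311%), the mean of unplaced scaffolds in day 1 replicate 5 (67.8%), and a single library in 3 named tiles: week 1 replicate 3 at 10.2% on chromosome 20 at 10974001, NSC replicate 1 at 48.1% on chromosome 19 at 54823001, and day 1 replicate 2 at 32.4% on chromosome 13 at 96281001. The effects at week 1 and day 1 against NSC differed, by the test of the difference itself and by at least 10 points, in 3 tiles, by -24.6 points on chromosome 18 at 68973001, 16.1 points on chromosome 1 at 123990001 and 28.8 points on chromosome 15 at 28212001. A further tile, on chromosome 19 at 54823001, had an edgeR adjusted p of 0.0438 with a difference of -9.30 points.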

How the results depend on the processing

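The 3 further alternatives for tiles (at least 5 reads in at least 3 libraries per group, and 2 without day 1 replicate 2), all for the shared calls and all for the classes were added after seeing the data. Means were not run with the coverage limit or cytosines in at least 3 libraries per group. Where computed, the day 1 mean exceeded NSC by 2.62 points (at least 20 reads) to 6.83 (reads pooled) and 10.4 (own cytosines). Leaving out each library gave 2.98 to 3.23 points, 1.11 to 1.79 (week 1 against NSC) and -2.0 to -1.32 (week 1 against day 1). The week 1 mean passed against NSC with at least 5 reads (2.07 points), reads pooled (3.65) and thinning (1.31), and did not with at least 20 reads (0.826) or own cytosines (5.50). The week 1 mean no longer passed against day 1 with each library's own cytosines (-4.94) and with reads pooled (-3.18); the cause was not tested. Leaving out each library gave 146 to 163 tiles for day 1 against NSC, 90 to 120 for week 1 against NSC, 2 to 4 for week 1 against day 1, and 82 to 109 shared tiles. The coverage limit kept 4422 of the 7716 cytosines, and why coverage was so high at the others was not tested. With it, the share of tiles called fell from 17.9% to 13.3% for day 1 against NSC. For week 1 against NSC it fell from 12.7% to 7.04%. Without day 1 replicate 2, cytosines selected again, these shares rose to 21.9% and 15.6%. Counts moved by over 1.5 times mostly with the number of tiles tested, with this share or with the threshold. In the order day 1 against NSC, week 1 against NSC and shared, they were 769, 478 and 414 with at least 5 reads (4656 tiles); 31, 25 and 21 with at least 20 reads (206); 64, 34 and 31 with the coverage limit (483); 2491, 1554 and 1266 with cytosines in at least 3 libraries per group (14484); 51, 36 and 33 with at least 5 cytosines (367); 7428, 4061 and 3089 with at least 5 reads in at least 3 libraries per group (65034); 1138, 809 and 697 without day 1 replicate 2, cytosines selected again (5185); 2495, 1598 and 1305 without it in the wider set (14484); 41, 33 and 27 with at least 25 points; and 283, 186 and 157 with no minimum difference. Thinning gave 75 tiles for week 1 against NSC and 58 shared. Week 1 against day 1 went from 3 tiles to 1 with at least 20 reads, thinning or 25 points, to 5 with quasi-binomial regression, to 0 with at least 5 reads in at least 3 libraries per group, where 4301 of 65034 tiles had an unadjusted edgeR p below 0.05 and no other tool was run, and to 6 without day 1 replicate 2; the cause was not tested. A setting that did not keep a named tile gave no value for it, and such gaps were not counted as losses. Each named tile against NSC therefore had 22 to 24 recomputed values. For the 12 named results against NSC, 275 of 275 recomputed values kept direction and call. For the 3 tiles between week 1 and day 1, 47 of 68 did and 21 lost the call, 18 of them for chromosome 1 at 123990001, which kept it in only 2 of the 13 fits without a library (day 1 replicate 3 or 5). The classes by the mean of the 3 groups were computed first and replaced after their results were known. With them and at least 5 reads, 2 class differences that had not passed changed sign, to -0.0317 (under 10%, week 1 against NSC) and -0.316 points (10 to 30%, week 1 against day 1). Promoters, gene lists and their alternatives were not run. No paired analysis was possible because replicate numbers were given in accession order. Depth limits the tests to well covered cytosines, many of which the coverage limit left out.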

Other observations

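The tests in this part were chosen after the data had been seen.

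The 39168 cytosines with 5 reads in all libraries were also grouped by how many cytosines were listed in their tile. The 16362 in tiles with 1 to 19 were at 71.9% ± 0.203 (SD, n = 4) in NSC, 76.9% ± 0.816 (SD, n = 5) at day 1 and 74.6% ± 1.29 (SD, n = 4) at week 1. Day 1 exceeded NSC by 5.04 points there, by 3.79 points in tiles with 20 to 39 and by 1.45 points in tiles with 40 to 79, each with an adjusted p of 0.0476 over 12 exact permutation tests. In these classes week 1 exceeded NSC by 2.72, 2.48 and 1.07 points (adjusted p = 0.0490, exact permutation tests). The 3826 cytosines in tiles with 80 or more were at 4.74% in NSC, and neither time passed there (0.337 and 0.197 points). Dense tiles have low methylation, and the difference between classes was not tested. Unplaced scaffolds, with 1541 cytosines, were at 62.1% ± 1.53 (SD, n = 4), 62.5% ± 2.99 (SD, n = 5) and 62.5% ± 1.81 (SD, n = 4), with exact permutation p of 0.952 and 0.80 against NSC.

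In the widest set of 65034 tiles some called tiles lay side by side. Runs of at least 3 called tiles of one direction, with starts at most 3000 bp apart, numbered 11 higher and 4 lower at day 1, and 3 higher and 1 lower at week 1. Shuffling the calls within chromosomes 1000 times gave means of 5.58, 0.073, 0.728 and 0.028 runs (adjusted permutation p = 0.04, 0.004, 0.04 and 0.04 over 4 tests). The shuffle takes all measured tiles as equally likely to be called. On chromosome 20 at 6284001 to 6288000 the 3 called of 4 measured tiles, with 24 cytosines, averaged 14.8% in NSC, 72.7% at day 1 and 72.4% at week 1. On chromosome 8 at 113990001 to 113994000 the 3 called of 4 measured tiles averaged 74.1%, 38.3% and 38.9%, on 15 cytosines, and the remaining tile moved the opposite way at week 1.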
